A study of Mus musculus with 4 samples.

How the data were processed

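Droplet-based single-cell RNA libraries were made from embryoid bodies of mouse embryonic stem cells at days 2, 8, 12 and 16, with polyadenylated RNA and Chromium 3' v3 gel beads, per the labels' protocols. Each of the 4 libraries holds 1 day. The deposited files hold raw UMI counts per gene and barcode that the authors made with Cell Ranger 7.1.0 and GRCm38, per the file headers and the submitters' processing notes. The annotation, the read settings and the strand use of that counting are not given in the sources used here. The files hold 6738 barcodes on day 2, 12557 on day 8, 13721 on day 12 and 13382 on day 16. Of 32285 features, 32235 were found by ID in a GENCODE annotation of GRCm38, from which the positions come, and 50 were not. The files pair IDs with symbols, and 38 symbols are shared by more than 1 feature.

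Barcodes were kept with at least 1000 UMIs, at least 500 genes, at most 15% mitochondrial UMIs and no doublet call by Scrublet as run in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). Scrublet's automatic threshold called 1 doublet on day 2, under the 0.5% set beforehand as a failure, so there the 363 highest scores were taken, 0.8% per 1000 barcodes. It called 413 on day 8, 324 on day 12 and 610 on day 16. This left 5153, 10565, 10599 and 11307 cells with 165806963, 173409310, 169905717 and 207558941 UMIs, and median genes per cell of 6505, 4009, 4331 and 4639. Across genes, which are not replicates, Pearson's r of log2 CPM plus 1 lay between 0.966 for days 2 and 8 and 0.994 for days 12 and 16.

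With 1 library per day there is no p-value, standard error or test across cells. For each of 4 comparisons of libraries, UMIs were summed over kept cells and scaled to CPM. Levels carry exact Poisson intervals and ratios exact intervals of 2 Poisson counts. Shares of cells carry exact Clopper-Pearson binomial intervals. All are 95% intervals of counting error. The ratio of mean Dlx2 UMIs in cells with at least 5 of them carries a 95% bootstrap interval over cells. It covers the sampling of cells only, and cells are not replicates of a day. A gene at 0 was set to a floor of 3 counts per library to give a lower bound. A total of 42 gene lists was fixed before the data were examined. A list member counts as measured with at least 5 CPM in the higher library, and as higher or lower from 2-fold on, which is a rule of size. The median log2 ratio of a list was placed among the medians of 10000 random lists of the same size matched on mean expression. That percentile describes these libraries. Genes named in the text are the 10 highest and 10 lowest ratios among genes with at least 50 CPM in the higher library, up to 4 members of each list with the largest ratios, Dlx1, Dlx2, Dlx5, Dlx6 and Tmpo, and 5 leading genes of each cluster. Predicted, mitochondrial and ribosomal protein genes were left out of the ratios. Genes outside that rule are Pou5f1, Barx1, Sox10 and Xist, and list members given in full where a list was split. They were named after their values were seen, as were the genes given for a single cluster of a class.

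Cells of all libraries were clustered together without batch integration, on log-normalised counts of 3000 variable genes, 30 principal components and 15 neighbours, with the Leiden method at resolution 1.0 (igraph 0.11.9). Marker genes of 23 cell classes were fixed beforehand. The rule that turns them into names was chosen after the clusters and their marker hits had been seen, and 2 orderings of candidate classes were weighed. A marker counted with at least 20 CPM and 2-fold over the other clusters, and a name needed at least 3 markers and 40% of the class's markers. With low UMI counts or with rival classes, the 10 genes of largest fold were also used. Ordering by the share of markers alone would have named the largest smooth muscle cluster a fibroblast. A cluster with 5.99% of day 8 cells and trophoblast as its best class was left without a name, since its 10 leading genes held more markers of another class. So was one with 0.811% of day 12 cells, for its low UMI counts and no marker among its 10 leading genes. A cluster mostly of 1 library may be that library and not a cell type. Levels within a class were computed for days with at least 50 of its cells. Cells with and without a Dlx2 UMI were compared after random thinning to 5000 UMIs, which left out 1109, 2137, 2506 and 1499 cells below that depth on the respective days. A gene was counted where at least 1% of the thinned cells of the library, with and without Dlx2 pooled, had it. This minimum and the 2-fold rule of those counts were set after the data were seen.

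The calling of ratios was tested on simulated Poisson counts with the means of the earlier library and the real library sizes. No variation between cultures or libraries was simulated, so the checks cover the calculation and counting error only. In each comparison, run on 10788 to 11412 measured genes, 50 of 50 genes changed 4-fold in either direction were called and 0 of 50 changed 1.5-fold, and intervals held the true fold for 88.0% or more of the changed genes of each size. Simulated cells of 3 classes, with all markers of the class set to the same level, were named as made, 400 of 400 each. Such clean groups do not show how well real clusters are named. Alternatives were all deposited barcodes, a stricter filter of 2000 genes and 10% mitochondrial UMIs, doublets kept, scaling by TMM factors (edgeR 4.0.16, R 4.3.3), means over cells of CPM per cell, minimum levels of 1 and 20 CPM, Leiden resolutions of 0.5 and 2.0, 50 components, thinned cells for clustering, each library clustered alone, and 2500 UMIs or no thinning for Dlx2. Removal of barcodes under 0.5% mitochondrial UMIs, 8.48%, 20.3%, 13.2% and 16.3% of the kept cells of the respective libraries, and the use of 1 cluster per class for levels within classes, the one with most of the class's cells on its first day, were added after seeing the data.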

Results

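Single-cell RNA sequencing was done on embryoid bodies, the aggregates that embryonic stem cells form when they differentiate in suspension. The mouse cells are labelled as overexpressing Dlx2, a homeobox transcription factor of the forebrain and the facial neural crest, and as induced with doxycycline. The series asks whether such cells, on the way to ectomesenchyme, the crest-derived mesenchyme of the face, pass through known steps of development. Libraries came from days 2, 8, 12 and 16, with 1 library per day, so no value below has a replicate check. No library without induction is used here, so each comparison sets days of one time course against each other. The counts held 187238049 unique molecular identifiers (UMIs) on day 2, 188770740 on day 8, 181619570 on day 12 and 229734017 on day 16. The cells kept numbered 5153, 10565, 10599 and 11307 on those days, with median UMIs per cell of 34135, 13795, 13919 and 16400. Levels are given as CPM, the usual scaling of counts to a common total, computed from the summed UMIs of the kept cells. Brackets hold 95% intervals, which cover counting error only and not differences between cultures or libraries. Gene positions refer to GRCm38.

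The level of Dlx2 in each library comes first, since the labels name it as the gene overexpressed. Dlx2 (ENSMUSG00000023391, chromosome 2, 71543408 to 71546754) was highest on day 2 and lower in each later library. It stood at 743 CPM [739 to 748] on day 2, 264 CPM [262 to 267] on day 8, 72.5 CPM [71.2 to 73.8] on day 12 and 19.7 CPM [19.1 to 20.3] on day 16. Day 2 was thus 2.81-fold above day 8, and 37.8-fold above day 16. With each cell thinned to 5000 UMIs, 51.2% of cells [49.6 to 52.7] had a Dlx2 UMI on day 2, 38.2% on day 8, 17.1% on day 12 and 6.80% [6.31 to 7.32] on day 16. The mean per cell with Dlx2 was also lower, at 8.43 UMIs on day 2, 4.61 on day 8, 2.67 on day 12 and 1.67 on day 16. Classes low in Dlx2, chosen as background after their values were seen, had a Dlx2 UMI in 9.69% of visceral endoderm cells [6.37 to 14.0] on day 8, and in 1.86% [0.687 to 4.01] on day 12 and 0.782% [0.391 to 1.40] on day 16 of parietal endoderm, a tissue that lines the yolk cavity. The median depth before thinning was 19629, 13394 and 15421 UMIs in those cells, against 17676, 18166 and 18314 in all thinned cells of the libraries. On day 2 no such class was found, and pluripotent cells, the only named class with at least 50 cells of that depth, had one in 63 of 259 cells, or 24.3%. On day 2, 90.2% of the Dlx2 UMIs lay in a single cluster with 39.2% of the cells. That cluster was led by Dlx1as and Dlx6os1, transcripts antisense to Dlx1 and Dlx6, with Plpp4, Uncx and Syt16. Of the other Dlx genes, Dlx1 stood at 4.44 CPM on day 2 and 1.54 CPM on day 16, Dlx3 at 23.0 and 2.93 CPM, Dlx5 at 10.7 and 6.89 CPM, and Dlx6 at 6.52 and 4.16 CPM. Counts do not separate the introduced copy from the cell's own Dlx2, and an introduced copy without the natural 3' end could be missed.

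**Figure D1:**
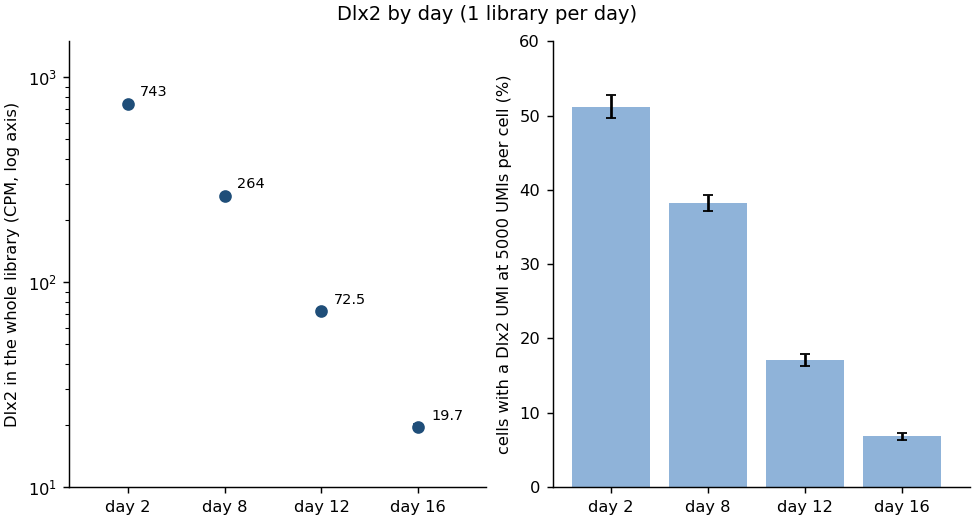
Left, Dlx2 in CPM of summed UMIs on a log axis for the library of each day, 743 on day 2 and 19.7 on day 16, with exact Poisson 95% intervals smaller than the points. Right, bars show the percent of cells with a Dlx2 UMI after thinning to 5000 UMIs, 51.2% on day 2 and 6.80% on day 16, with exact binomial 95% intervals.

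The comparison of days 2 and 8 asks how the aggregates had changed after the day of highest Dlx2. Genes of the trophoblast, the lineage of the placenta, were far higher on day 8: 10 of 11 measured members were at least 2-fold higher and none lower, with a median log2 ratio of 3.32 (percentile 100 among 10000 random lists matched on expression). Tpbpa (ENSMUSG00000033834, chromosome 13, 60938492 to 60941984), a marker of the spongiotrophoblast, had no UMI on day 2 and 497 CPM on day 8, at least 27470-fold higher against a floor of 3 UMIs. Ascl2, a regulator of that layer, went from 18.3 to 164 CPM, and Cdx2, a factor of the early trophectoderm, from 1.99 to 21.5 CPM. Among the 10 highest ratios stood Sct, which encodes secretin, from 17.2 to 1503 CPM (87.2-fold [84.0 to 90.5]), the adhesion gene Cdh5, from 0.0965 to 185 CPM, and Ceacam9, from 0.0302 to 59.1 CPM. The other highest ratios belonged to placental prolactins (Prl6a1, Prl2a1, Prl7d1) and Serpinb9 genes (Serpinb9g, Serpinb9e, Serpinb9b), near-identical families whose split of reads is uncertain. Prl2a1 had no UMI on day 2 and 80.3 CPM on day 8, and Serpinb9g had 1 UMI on day 2 and 190 CPM on day 8.

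The pluripotency list was not lower on day 8. Of 20 measured members, 8 were at least 2-fold higher and 2 lower, with a median log2 ratio of 0.58 (percentile 100). Dppa5a, an RNA-binding protein of stem cells, went from 1334 to 5984 CPM, Klf2 from 46.9 to 207 CPM, Tdgf1 from 35.1 to 124 CPM and Klf4 from 32.4 to 78.7 CPM, while Lin28a and Dppa3 were the lower members. Pou5f1 (ENSMUSG00000024406), the core pluripotency factor, was named after its values were seen, at 108 CPM on day 2, 148 on day 8, 184 on day 12 and 187 on day 16. Genes of the 2-cell-like state, a rare state of stem cells resembling the early embryo, were higher in 8 of 8 measured members. Zscan4d had 2 UMIs on day 2 and 45.7 CPM on day 8 (3791-fold [1049 to 31310]); its family also holds near-identical copies. Hypoxia and glycolysis genes were higher in 13 of 15 members (median log2 ratio 1.73, percentile 100), with Bnip3, a mitophagy receptor, from 12.9 to 79.5 CPM and Ankrd37 from 10.6 to 67.0 CPM. Dissociation stress genes moved with them, 8 of 15 higher and none lower (median 1.43), with Fos, an immediate early gene, from 15.5 to 95.2 CPM. Endothelium genes were higher in 4 of 7 measured members and visceral endoderm genes in 5 of 9, with 1 of 9 lower.

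The ectomesenchyme list was lower on day 8. Of 15 measured members 7 were at least 2-fold lower and 2 higher, with a median log2 ratio of −0.91 (percentile 0.1). Lhx6, a LIM homeobox gene of the jaw, was 6.91-fold lower (8.96 to 1.30 CPM) and Msx1, a homeobox gene of the facial primordia, 4.22-fold lower (5.47 to 1.30 CPM). Msx2 went from 58.9 to 20.3 CPM and Pdgfra, a growth factor receptor of mesenchyme, from 38.3 to 17.3 CPM. Prrx1 (ENSMUSG00000026586), a mesenchymal homeobox gene, went the other way, from 2.77 to 19.5 CPM (7.02-fold [6.37 to 7.76]). Of the 10 lowest ratios, Npas1, a neuronal transcription factor, was 35.7-fold lower, Sorbs2 20.4-fold, Plpp4 16.7-fold, Dlx1as 16.1-fold, Coch 14.5-fold and the homeobox gene Uncx 13.9-fold. Ntm was 10.6-fold lower, Kcnq3 9.70-fold, Lmo1 9.24-fold and the imprinted gene Mest 9.18-fold, from 858 to 93.5 CPM. WNT genes were lower in 5 of 10 members and higher in 2 (median −1.30), with Wnt6 from 11.0 to 2.57 CPM and Axin2 from 8.33 to 2.34 CPM. Over all list genes, 109 of 369 were at least 2-fold higher and 60 lower, against 1194 and 1136 of 11568 among all measured genes. Day 2 cells were deeper, at a median of 34135 against 13795 UMIs, and with only genes of at least 20 CPM counted, the WNT median became 0.74 and the ectomesenchyme list 0 higher and 3 lower; strand use of the counting, which Dlx1as depends on, is not given in the sources used here.

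From day 8 to day 12, genes of contractile, matrix-rich and extraembryonic endoderm cells were higher. Smooth muscle genes were at least 2-fold higher in 8 of 10 measured members and lower in none (median log2 ratio 2.73, percentile 100). Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), smooth muscle actin, went from 0.767 to 394 CPM (513-fold [433 to 613]), and the actin-binding gene Tagln from 2.66 to 293 CPM (110-fold [100 to 121]). Collagen and fibroblast matrix genes were higher in 14 of 19 members and lower in none (median 1.35), with Col1a1, the main chain of type I collagen, from 9.04 to 88.7 CPM. Mesenchymal transition genes were higher in 10 of 16 (median 1.14), with Vim, the intermediate filament of mesenchyme, from 39.6 to 254 CPM. Parietal endoderm genes were higher in 10 of 13 (median 2.19), with the basement membrane genes Lama1 from 34.8 to 245 CPM and Col4a1 from 87.8 to 471 CPM. Visceral and yolk-sac endoderm genes were higher in 11 of 14 (median 1.96), with the transport proteins Ttr from 4.83 to 81.3 CPM and Rbp4 from 6.28 to 56.5 CPM. Pga5, S100g and Bc1 also ranked among the 10 highest, at 10.6-fold, 9.23-fold and 10.2-fold.

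The ectomesenchyme list was higher on day 12. Of 17 measured members 8 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.92 (percentile 100); 5 were higher by means over cells and 3 with only genes of at least 20 CPM counted. Hand2, a factor of the lower jaw and the heart, went from 2.32 to 9.91 CPM, Meis2, a homeobox gene of crest cells, from 47.8 to 182 CPM, and Twist1, a regulator of crest mesenchyme, from 10.8 to 23.0 CPM. The lower member was Dlx3, from 14.3 to 3.92 CPM. Formative epiblast genes were higher in 5 of 11 members, with Fgf5, a marker of that stage, from 2.69 to 11.1 CPM. Trophoblast genes were lower in 5 of 12 members and higher in 1 (median −0.72, percentile 0.0), though Prl8a9 and Prl7b1 were 17.5-fold and 12.2-fold higher. Genes of the 2-cell-like state were lower in 7 of 8. The 10 lowest ratios were Slc24a5 (4.63-fold lower), the cell cycle regulator Rgcc (4.27-fold), Dlx2 (3.65-fold), Jam2 (3.38-fold), Gabarapl2 (3.32-fold), the tetraspanin Cd9 (3.28-fold), the transcription factor Cebpb (3.14-fold), Fdx1 (3.02-fold), Ankrd37 (2.93-fold) and Batf3 (2.91-fold). Scaling by the trimmed mean of M values (TMM), which assumes most genes do not change, moved every log2 ratio of these days by −0.21; 122 of 413 list genes were at least 2-fold higher and 24 lower without it, and 101 of 410 higher and 40 lower with it. Higher genes thus made up 83.6% of the changed list genes, or 71.6% with TMM. Among all 11665 measured genes 907 were higher and 240 lower.

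From day 12 to day 16, contractile and parietal endoderm genes were higher again and placental genes lower. Smooth muscle genes were at least 2-fold higher in 6 of 11 members (median log2 ratio 1.23, percentile 100), with Acta2 from 394 to 1124 CPM and Tagln from 293 to 987 CPM (3.37-fold [3.33 to 3.40]). Parietal endoderm genes were higher in 9 of 14 and lower in none (percentile 100), with Lama1 from 245 to 647 CPM, Fst, the activin antagonist follistatin, from 29.5 to 108 CPM, and Col4a1 from 471 to 1182 CPM. The highest ratios were those of the gastrokine genes, Gkn2 (ENSMUSG00000030049) from 7.62 to 154 CPM (20.2-fold [19.1 to 21.4]) and Gkn1 from 5.52 to 76.0 CPM. Fxyd3 followed at 6.93-fold, the tetraspanin Tspan8 at 4.18-fold, the endoderm factor Sox17 at 3.51-fold, Arhgap6 at 3.47-fold, the matrix gene Ccn2 at 3.45-fold and Hs3st1, an enzyme of heparan sulfate, at 3.38-fold. Collagen genes were higher in 4 of 22 members and lower in none (median 0.53), with Col1a1 from 88.7 to 260 CPM. The ectomesenchyme list had 2 of 16 members higher and none lower, with Hand2 from 9.91 to 20.6 CPM and a median of 0.26 (percentile 100).

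Trophoblast genes were lower in 6 of 11 members on day 16 and higher in none (median −1.22, percentile 0.0). Tpbpa was 6.74-fold lower (809 to 120 CPM), Sct 5.85-fold (1509 to 258 CPM) and Cdx2 3.21-fold (20.6 to 6.44 CPM). Prl7b1, Prl2c5, Serpinb9g, Ceacam9, Prl2a1 and Prl8a9 were 5.29-fold to 7.31-fold lower, with the same uncertainty for copies. Tnfrsf9, a receptor of the tumour necrosis factor family, was 7.76-fold lower, and the replication-dependent histone gene Hist1h2ap 6.66-fold. Visceral and yolk-sac endoderm genes were lower in 7 of 14 and higher in 2 (median −0.92), with Afp, alpha-fetoprotein, from 14.6 to 3.54 CPM and Ttr from 81.3 to 32.4 CPM. No pluripotency gene was at least 2-fold lower and 1 of 20, Klf4, was higher. Over all list genes 44 of 431 were higher and 29 lower, while among all 11595 measured genes 165 were higher and 262 lower.

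Set against day 2, the day 16 library was rich in mesenchymal, contractile and endodermal transcripts, while the genes of the day 2 cluster with most Dlx2 UMIs were low. Acta2 had 18 UMIs on day 2 and was 10357-fold higher [6553 to 17476] on day 16. Col3a1 (ENSMUSG00000026043), the main chain of type III collagen, was 4993-fold higher [1950 to 18327], and Gkn2 and Gkn1 at least 8501-fold and 4198-fold. Aqp8, a water channel, was 1744-fold higher, Spink1, a trypsin inhibitor, 1042-fold, Sox17 473-fold, Col1a1 264-fold [227 to 310] and Srgn, a secretory granule proteoglycan, 182-fold. All 14 measured parietal endoderm genes were at least 2-fold higher (median log2 ratio 4.17), as were 18 of 22 collagen genes (median 2.79), 15 of 17 mesenchymal transition genes (median 2.98), 10 of 11 smooth muscle genes (median 3.07) and 7 of 11 neuron genes (median 1.14). Each of these medians lay at percentile 99.9 or above, and in these lists 1 member, of the neuron list, was lower. Epithelial genes were lower in 6 of 17 members and higher in none (median −0.76, percentile 0.0), with Cdh1, epithelial cadherin, from 252 to 71.9 CPM.

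Ectomesenchyme genes went both ways between days 2 and 16: 10 of 20 measured members were at least 2-fold higher and 5 lower (median 0.54, percentile 99.6). The higher members were Foxc1, Twist2, Meis2, Twist1, Meis1, Ednra, Hand2, Prrx2, Edn1 and Prrx1, which went from 2.77 to 44.7 CPM (16.1-fold [14.7 to 17.8]). The lower members were Dlx3 (7.85-fold), Msx2 (4.72-fold), Lhx6 (4.44-fold), Msx1 and Barx1, a factor of jaw and tooth mesenchyme. Migratory crest genes were higher in 6 of 11 and lower in 1 (median 1.85, percentile 100), with Nr2f2 31.0-fold higher and Ngfr, a receptor of crest cells, the lower member. The 10 lowest ratios were Dlx2 (37.8-fold lower), Uncx (37.5-fold), Plpp4 (34.8-fold), the keratin Krt25 (33.8-fold), Dlx1as (29.3-fold), Dlx6os1 (22.7-fold), Cacnb4 (12.8-fold), Npas1 (12.7-fold), Stk32a (12.2-fold) and Ebf3 (12.1-fold). Of all list genes 188 of 430 were higher and 28 lower, against 1330 and 674 of 11713 among all measured genes. The ectomesenchyme counts varied with the minimum level, at 17 higher members with at least 1 CPM and 6 with at least 20 CPM.

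Tmpo (ENSMUSG00000019961, chromosome 10, 91147571 to 91181315) encodes LAP2 proteins, among them the nucleoplasmic isoform that the series title names. It stood at 159 CPM [158 to 161] on day 2, 125 on day 8, 153 on day 12 and 163 [162 to 165] on day 16, a ratio of 1.03 [1.01 to 1.04] between the first and last day. Counts from 3' ends summed per gene do not tell its isoforms apart. In the nuclear lamina list 1 of 15 measured members was at least 2-fold higher between days 2 and 16 and none lower (median 0.07). That member was Lmna, which encodes lamins A and C, from 31.1 to 85.8 CPM (2.75-fold [2.67 to 2.84]). Between days 2 and 8, Syne1 and Sun2, which link the lamina to the cytoskeleton, were lower. Of 23 chromatin genes 1 was higher and none lower between days 2 and 16 (median −0.07, percentile 15.9).

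**Figure D2:**
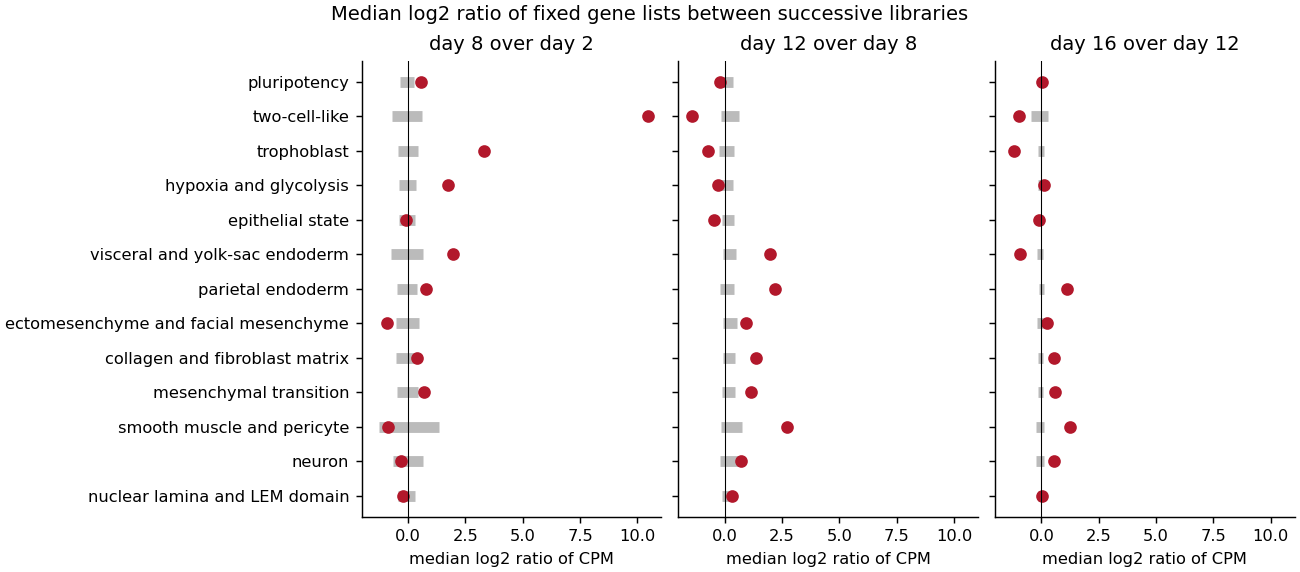
Red points give the median log2 CPM ratio of the measured members of 13 gene lists between neighbouring days, day 8 over day 2, day 12 over day 8 and day 16 over day 12 from left to right, and grey bars the central 95% range of the medians of 10000 random lists matched on expression. The ectomesenchyme median lies at −0.91, 0.92 and 0.26 in these panels, and the trophoblast median at 3.32, −0.72 and −1.22.

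Cells of all libraries were clustered together, and clusters were named from marker genes fixed before the data were examined by a rule chosen afterwards. Trophoblast cells made up 43.9% of the day 8 cells [42.9 to 44.8], 20.2% on day 12 and 8.08% on day 16, against 0.0194% on day 2. Pluripotent cells made up 6.44% on day 2, 21.3% on day 8, 16.5% on day 12 and 19.4% on day 16. At 5000 UMIs per cell, 24.7%, 30.2%, 38.7% and 36.6% of the cells of these libraries had a Pou5f1 UMI. On day 2, 760 such cells lay in unnamed clusters and 236 in the pluripotent class, so the day 2 share of the class leaves out most of them. A cluster of the pluripotent class led by Dppa3, Tdrd12, Rims1, Mylpf and Nr5a2 held 0.155%, 0.521%, 11.1% and 9.12% of these libraries. It met 8 of 10 pluripotent markers, but Dppa3 and Prdm1 among its 10 leading genes are on the germ cell list. Fibroblast cells, the class rich in collagens, went from 0.155% on day 2 to 8.72% on day 8, 11.8% on day 12 and 14.8% on day 16. Between days 8 and 16 its cluster led by Ncam2 and Col6a3 went from 8.415% to 3.75%. The other cluster of the class, led by Pcdh11x and Shisa3, went from 0.303% to 11.0%. Smooth muscle or pericyte cells stood at 0.227% on day 8, 5.27% on day 12 and 13.9% [13.2 to 14.5] on day 16, and parietal endoderm at 0.0757%, 3.62% and 13.5%. Visceral or yolk-sac endoderm was most frequent on day 12, at 9.53%, against 2.72% on day 8 and 2.55% on day 16. Neurons, led by Fabp7, Pou3f2 and Nhlh2, were 1.96% of cells on day 12 and 4.55% [4.17 to 4.95] on day 16, with 0 of 10565 cells [0 to 0.0349] on day 8. Cells of the 2-cell-like class made up 4.22% on day 8 and 1.07% on day 16, with 0 of 5153 on day 2. Most day 2 cells, 93.1%, lay in clusters left without a name, as did 18.9%, 28.6% and 22.3% of the later libraries. An unnamed cluster led by Ctsq, Prl2b1 and Ctsj did meet 5 of 10 trophoblast markers. It held 5.99% of day 8 and 2.87% of day 12 cells, which the trophoblast shares leave out. A cluster with 9.77% of the day 12 cells and no name was led by Trh, Pim2, Lef1, Pou3f1 and Lefty1. No cluster was named facial mesenchyme as clustered here. Each cluster takes a single name, so a cluster named for another class could still have met the facial mesenchyme markers. With cells thinned first, a cluster with 5.19% of day 8, 2.85% of day 12 and 0.795% of day 16 cells took this name. With each library alone, 5.38% of day 8 and 5.56% of day 12 cells took it. Clusters with a median under 5000 UMIs held 1912 of 4636 trophoblast cells on day 8, 558 of 1010 visceral endoderm cells on day 12 and 449 of 1570 smooth muscle cells on day 16. The cells of each class outside these clusters were still counted against all kept cells of the day. On that count trophoblast made up 25.8%, 11.3% and 5.27% of days 8, 12 and 16, and visceral endoderm 2.46%, 4.27% and 1.57%. Smooth muscle made up 3.87% of day 12 and 9.91% of day 16. These shares restate the marker genes of the lists and shift with clustering: trophoblast on day 8 ranged from 28.9% to 55.5%, and to 0 with each library clustered alone, and pluripotent cells on day 8 were 0.435% at a coarser resolution, 4.57% with doublets kept and 4.36% with 50 components. Across the other settings neurons on day 16 ranged from 0.930% to 1.57%, save for the coarser resolution with 4.53%. Across all of these settings fibroblasts on day 16 ranged from 3.64% to 16.2%, smooth muscle from 7.35% to 26.2%, and visceral endoderm on day 12 from 0 to 10.01%.

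**Figure D3:**
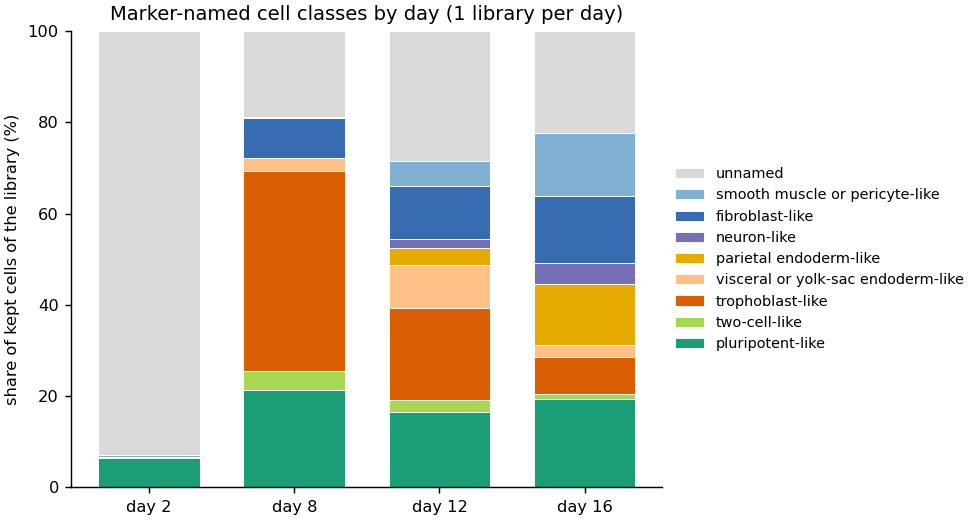
Stacked bars give the percent of kept cells in each of 8 classes named from marker genes, and in unnamed clusters, for the library of each day. Trophoblast takes 43.9% on day 8, and unnamed clusters take 93.1% on day 2.

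Levels within a class on different days were compared next, and a class can hold clusters whose shares change between days. In trophoblast Dlx2 went from 325 to 31.7 CPM between days 8 and 16, and in the pluripotent class from 93.6 CPM on day 2 to 9.65 on day 16. Between days 8 and 16 it went from 200 to 46.1 CPM in the 2-cell-like class. The classes taken as background above were lower as well, visceral endoderm with 33.2 and 7.09 CPM on days 8 and 16 and parietal endoderm with 6.85 and 2.28 CPM on days 12 and 16, and free RNA adds to every level here. In neurons it was low on both days, at 5.59 and 4.84 CPM. The fibroblast class was made of 2 clusters, looked at apart after the class values were seen. A first cluster held 889 of the 921 fibroblast cells on day 8 and 424 of 1669 on day 16, and the other, led by Pcdh11x and Shisa3, held 32 and 1245. In the first cluster Dlx2 went from 921 CPM [899 to 942] on day 8 to 308 on day 12 and 138 [127 to 150] on day 16, against 889, 169 and 33.5 CPM in the whole class. Between days 8 and 16 of that cluster, 16 of 23 measured collagen and fibroblast matrix genes were at least 2-fold higher and none lower (median log2 ratio 1.53, percentile 100). The fibroblasts also held facial genes, although collagens and Pdgfra, not these, named the class. In the first cluster 5 of 27 measured ectomesenchyme genes were at least 2-fold higher and 1 lower (median 0.06, percentile 44.2), against 11 of 30 higher and 10 lower in the whole class (median −0.13, percentile 15.7). There Prrx1 stood at 393 CPM on day 8 and 415 on day 16, Meis2 at 365 and 379, Hand2 at 31.4 and 53.3 and Barx1 at 429 and 247. The other cluster held 143 CPM of Prrx1, 955 of Meis2, 111 of Hand2 and 41.5 of Barx1 on day 16, so ratios of the whole class compare clusters as well as days. Of the largest ratios in the first cluster, the matrix calcification inhibitor Mgp was 63.1-fold higher, Tagln 61.4-fold, Acta2 48.3-fold, and the interferon-induced genes Cxcl10 24.6-fold and Ifit3 18.1-fold. Ghrh, growth hormone releasing hormone, was 9.66-fold lower and Ankrd37 went from 309 to 47.5 CPM. Sox10, the regulator of early and glial crest, had 0 CPM on day 8 and 0.221 CPM on day 16 in the whole class. Barx1 and Sox10 were picked after their values were seen.

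In the pluripotent class, 2 of 20 pluripotency genes were at least 2-fold higher on day 16 than on day 2 and 2 lower (median −0.15). Of its clusters, 2 held 172 and 152 of the 332 day 2 cells. Another, led by Dppa3, Tdrd12, Rims1, Mylpf and Nr5a2, held 8 on day 2 and 1031 of 2191 on day 16. Ratios of the whole class thus compare clusters as well as days. Within the cluster of 172, no pluripotency gene was at least 2-fold higher and 2 of 20 were lower (median 0.09), Dlx2 was 7.41-fold lower and Lefty1, a nodal antagonist, went from 11.3 to 167 CPM. In the neuron class 13 of 19 neuron genes were at least 2-fold higher on day 16 than on day 12 and none lower (median 1.59), with Fabp7, a fatty acid binding protein of glia and progenitors, from 54.5 to 992 CPM. In parietal endoderm Gkn2 went from 237 to 1218 CPM between these days. In visceral endoderm, Afp went from 2.61 CPM on day 8 to 157 on day 16 and Rbp4 from 70.0 to 993 CPM. Within-class values of abundant genes hold free RNA: on day 16 an Acta2 UMI was found at 5000 UMIs in 22.3% to 35.7% of the other classes and 45.3% of fibroblasts, against 82.1% of smooth muscle cells, and on day 12 a Tpbpa UMI in 30.3% to 43.1% of the other classes, against 72.4% of trophoblast cells.

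Cells with and without a Dlx2 UMI were then compared within each library at 5000 UMIs per cell. On day 2, 14 of 21 ectomesenchyme genes were detected at least 2-fold more often in the 2069 cells with Dlx2 than in the 1975 without, and 1, Dlx3, less often. Lhx6 was found in 6.91% [5.86 to 8.09] against 0.354% [0.143 to 0.729] of cells, Pdgfra in 23.3% [21.5 to 25.2] against 1.77% [1.24 to 2.46], Msx2 in 31.6% against 10.2% and Msx1 in 3.72% against 0.911%. Of 19 pluripotency genes 13 were found at least 2-fold less often with Dlx2 and none more often. Klf2 was found in 142 cells with Dlx2 and 395 without, a share 2.91-fold lower with Dlx2. Tfcp2l1, a factor of the naive state, was found in 14.4% against 37.1% of cells, and Pou5f1, not among the genes picked beforehand, in 14.2% against 35.7%. On day 8 the counts were 12 of 21 ectomesenchyme genes more often and 13 of 20 pluripotency genes less often, with Dlx5 in 7.01% against 1.13% and Prrx1 in 10.6% against 4.34%. On day 12 they were 11 of 27 and 5 of 20, and on day 16 they were 9 of 28, with 2 less often, and 1 of 20. Day 16 cells with Dlx2 more often had Dlx1, in 4.05% against 0.624%, and Dlx5, in 10.9% against 2.87%. Tmpo was found slightly less often with Dlx2 in each library, in 48.5% against 53.3% on day 2 and 45.7% against 52.3% on day 16, and of the 15 lamina genes 1, Syne1 on day 2, passed 2-fold in any library, in 9.28% against 3.09%. Without thinning, the pluripotency genes found less often numbered 0 on day 2, 3 on day 8, 0 on day 12 and 0 on day 16, while the ectomesenchyme genes found more often on day 2 numbered 23; with 2500 UMIs they numbered 4 on day 12. Cells with Dlx2 also differ in class from cells without, so these shares compare kinds of cells as well, and free RNA adds to the cells with a UMI of each gene.

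**Figure D4:**
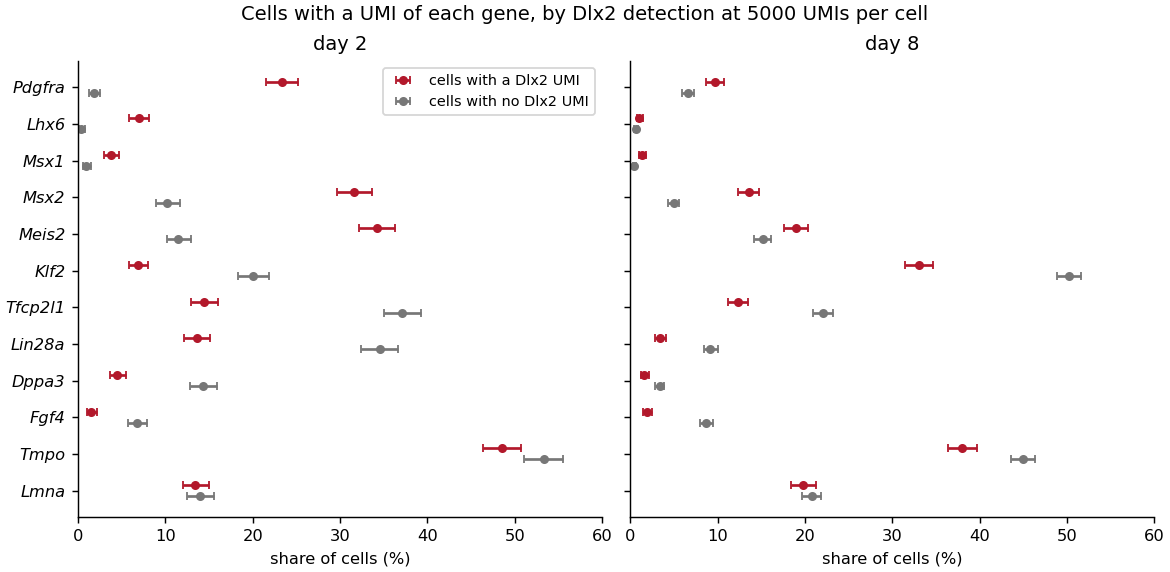
Points give the percent of cells, thinned to 5000 UMIs, with a UMI of each gene on days 2 and 8, in red for cells with a Dlx2 UMI and in grey for cells without, with exact binomial 95% intervals. On day 2 Pdgfra stands at 23.3% against 1.77% and Tfcp2l1 at 14.4% against 37.1%.

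Hox genes set the position of cells along the body, and the crest of the face in front of the second arch is known to lack them. Summed Hox genes of paralogue groups 1 to 3 stood at 6.83 CPM on day 2, 30.5 on day 8, 70.4 on day 12 and 51.9 on day 16. Groups 4 to 9 stood at 45.9, 33.6, 110 and 117 CPM on these days, and groups 10 to 13 at 12.6, 5.97, 9.72 and 15.5 CPM. Between days 8 and 12, 8 of 8 measured genes of groups 4 to 9 were at least 2-fold higher (median log2 ratio 1.77, percentile 100), and Hoxb2, a gene of the hindbrain and second arch, went from 12.8 to 25.7 CPM. The fibroblast class held 121 CPM of groups 1 to 3 on day 8, 142 on day 12 and 112 on day 16, and 190, 301 and 256 CPM of groups 4 to 9. Neurons held more, at 372 CPM of groups 1 to 3 and 864 CPM of groups 4 to 9 on day 16.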

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

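The tests on Dlx2 below, those that compare shares of cells with a UMI of Pou5f1 or Tpbpa, and the look at Xist were chosen only after the result was seen; the other tests were written before their own values, but after the levels of the genes they use, had been seen.

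Dlx2 was lower in each later library, 37.8-fold between days 2 and 16. A change in the shares of clusters as the whole cause is argued against between days 8 and 16. All 16 clusters with at least 50 cells on both days held 98.9% of the day 8 Dlx2 UMIs. In them Dlx2 was 2.135-fold to 23.8-fold lower on day 16, with a median ratio of 5.62, though free RNA adds to these levels. In 5 of them, with 71.5% of these UMIs, the day 8 level was above that of barcodes outside the cell filter. There Dlx2 was 2.92-fold to 23.8-fold lower, or to 13.3-fold without a cluster of 99 cells with 0.229% of these UMIs, with a median ratio of 8.89. These 5 were picked on a value compared. The day 8 library also held 468 barcodes over 15% mitochondrial UMIs, so that limit is not free RNA alone. Fewer UMIs per cell was looked at in thinned cells, whose mean of Dlx2 UMIs was 38.0-fold lower on day 16 at the same 5000 UMIs. CPM is already scaled to total UMIs, so this mean restates the CPM ratio and is no separate support. For fewer positive cells at an unchanged level, cells were picked for at least 5 Dlx2 UMIs at that depth, 1112 on day 2 and 31 on day 16. They held 1.83-fold fewer on day 16 (bootstrap interval over cells 1.57 to 2.15). That interval does not cover the difference between 2 single libraries. The cells were picked on the value compared, and the cluster with 90.2% of the Dlx2 UMIs on day 2 held 3.82% on day 16. This explanation thus stays open. Between days 2 and 8 the shares of clusters and the number of positive cells stay open too. The 4 clusters on both days had a median ratio of 1.07 but held 5.07% of the day 2 Dlx2 UMIs. Positive cells held 1.83-fold fewer Dlx2 UMIs on day 8, though free RNA adds weak positive cells and those with at least 5 UMIs held 1.24-fold fewer. Also open are weaker induction, silencing of the introduced copy, outgrowth of cells that carry less of it, and a difference between the 4 single libraries, none of which was tested.

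Pluripotency genes were not lower after day 2, with Pou5f1 at 108 CPM on day 2 and 187 CPM on day 16. Free RNA spread alike over cells is argued against by 298 cells with at least 5 Pou5f1 UMIs on day 16, where a single Poisson mean gives 16.3, a ratio of 18.2. In the same cells 36.6% had a Pou5f1 UMI, where that mean gives 56.4%, 1.54-fold more. Low-quality barcodes are argued against by the stricter cell filter, which left the day 16 over day 2 ratio at 1.76. It may be that undifferentiated cells persisted or outgrew others, which embryoid bodies without induction would be needed to test. The cells named pluripotent did not stay in the same clusters, as a cluster led by Dppa3 and Tdrd12 held 8 on day 2 and 1031 on day 16. Part of that class on day 16 thus need not be of the day 2 kind.

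Trophoblast genes were higher on day 8 than on day 2, in 10 of 11 measured members, with Tpbpa at 0 UMIs on day 2 and 497 CPM on day 8. Cells of the other sex from another source stay open: 4 Y-linked genes stood at 3.40 CPM [2.97 to 3.88] in the trophoblast class and 3.32 CPM [2.84 to 3.87] in the pluripotent class of day 8, a ratio of 1.02, but this is below the minimum of 5 CPM and all but 3 UMIs of that library came from Ddx3y, while Xist, the RNA of the silenced X chromosome, stood at 14.2 CPM [13.3 to 15.2] and 1.92 CPM [1.56 to 2.35]. For free RNA spread alike, the criterion written before, cells with at least 5 Tpbpa UMIs, came out on the side of free RNA, at 774 cells against 728 expected, a ratio of 1.06; with a mean of 2.32 UMIs per cell a Poisson spread itself gives many such cells, so that count cannot separate the cases. The share of cells with a Tpbpa UMI, 20.3% where a single Poisson mean gives 90.2%, 4.44-fold more, argues against free RNA as the whole source. Formation of trophoblast by the induced cells and another source of cells both stay open, and embryoid bodies without induction would be needed to test them.

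Other results stood out and are given as values; the use of non-overlapping intervals for shares of cells was settled after the data were seen. Barcodes outside the cell filter, used above only as a limit for free RNA and among all deposited barcodes, held Dlx2 above the limit that a count of 0 allows, at 251 CPM [231 to 273] on day 2, 278 CPM [254 to 304] on day 8, 64.9 CPM [55.3 to 75.7] on day 12 and 29.4 CPM [21.6 to 38.9] on day 16. The ratio of the share of cells with a gene, with Dlx2 over without, took opposite sides of 1 on different days, with intervals of the shares that did not overlap on either day. For Meis1 it was 1.95 on day 2 and 0.669 on day 16, for Meis2 2.98 on day 2 and 0.880 on day 12, and for Klf4 0.687 on day 2 and 1.47 on day 12. These differences between days were not tested.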

How the results depend on the processing

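Among the tests below, removal of barcodes with low mitochondrial share and the use of 1 cluster per class were chosen after seeing the data; the rest were planned. No paired analysis was possible because each day has 1 library and no result comes from a test. Of 30 values of Dlx2 under alternatives 11 stayed within counting error and 19 moved, none in direction, and of 9 Hox values 7 stayed. By the same rule 2844 of 3918 values of named genes stayed, with none reversed, and 133 of 280 class shares. List counts and list medians were called the same within 1.5-fold, which is a rule of size and not counting error. By that rule 2446 of 2752 list counts and 1236 of 1310 list medians stayed, and 12 medians reversed. Dlx2 on day 2, 743 CPM, was 768 with TMM factors, 726 with all deposited barcodes, 732 with doublets kept, 737 without low-mitochondrial barcodes and 918 as a mean over cells; its day 2 over day 16 ratio, 37.8, was 39.9 with TMM. The day 16 over day 2 ratio of Hox groups 4 to 9, 2.55, was 2.41 with TMM, and that of groups 10 to 13, 1.23, was 1.14 without low-mitochondrial barcodes. Except where a minimum level counts fewer or more genes by construction, the cause was not tested.

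A minimum of 20 CPM gave, over all list genes, 63 higher and 30 lower from day 2 to 8, 57 higher from day 8 to 12, 28 higher and 18 lower from day 12 to 16, and 108 higher and 14 lower from day 2 to 16; 1 CPM gave 92 lower from day 2 to 8, and TMM 40 lower from day 8 to 12. For ectomesenchyme genes, 1 CPM gave 5 higher from day 2 to 8, 4 from day 12 to 16 and 17 from day 2 to 16; 20 CPM gave 0 higher and 3 lower from day 2 to 8, 3 higher and 0 lower from day 8 to 12, 1 higher from day 12 to 16, and 6 higher and 3 lower from day 2 to 16; means over cells gave 5 higher from day 8 to 12 and 3 lower from day 2 to 16. Medians reversed with 20 CPM were those of neural progenitor (0.41), germ cell (−0.31), TGF-beta (−0.18) and WNT genes (0.74) from day 2 to 8, primitive streak from day 8 to 12 (−1.18), endothelium from day 12 to 16 (−0.30), and skeletal muscle (−1.40) and erythroid genes (−1.42) from day 2 to 16. With 1 CPM, primitive streak from day 2 to 8 (−0.59), gut endoderm from day 12 to 16 (−0.12) and surface ectoderm from day 2 to 16 (0.15) reversed, and without low-mitochondrial barcodes erythroid genes from day 2 to 16 (−1.41).

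With resolution 0.5, pluripotent cells on day 8 were 0.435%, fibroblasts on day 16 3.64%, smooth muscle on day 16 26.2%, visceral endoderm on day 12 0%, parietal endoderm on day 16 15.1% and trophoblast on day 8 55.5%. With resolution 2.0, neurons on day 16 were 1.44%, smooth muscle 8.19% and trophoblast 28.9%. With doublets kept, pluripotent cells were 4.57%, neurons 1.57%, visceral endoderm 4.64%, parietal endoderm 15.8% and trophoblast 29.9%. With 50 components, pluripotent cells were 4.36%, neurons 1.43%, fibroblasts 13.4%, visceral endoderm 5.42% and trophoblast 45.6%. With thinned cells, the shares were 22.1% pluripotent, 1.18% neuron, 13.7% fibroblast, 12.8% smooth muscle, 4.71% visceral, 14.6% parietal and 33.3% trophoblast. Without low-mitochondrial barcodes they were 0.930% neuron, 8.21% smooth muscle, 4.30% visceral, 15.7% parietal and 49.5% trophoblast. With each library alone, neurons were 1.45%, fibroblasts 16.2%, smooth muscle 7.35%, visceral endoderm 2.44% and trophoblast 0%; a marker common to most of a library then misses its 2-fold by construction. Facial mesenchyme, named for 0 cells as reported, took 2.85% of day 12 with thinned cells or without low-mitochondrial barcodes and 5.56% with each library alone. With classes of resolution 2.0, the first over last day ratio of Dlx2 was 7.29 in pluripotent cells, 3.37 in smooth muscle and 16.5 in trophoblast, and 13.4 in trophoblast with doublets kept. With 1 cluster per class, the one with most of its cells on its first day, it was 7.41 in pluripotent cells, 6.67 in fibroblasts and 13.3 in trophoblast. Without thinning, ectomesenchyme genes found more often with Dlx2 on day 2 were 23, and pluripotency genes found less often 0 on day 2, 3 on day 8, 0 on day 12 and 0 on day 16; with 2500 UMIs, 4 ectomesenchyme genes passed on day 12. The number of cells limits the shares: 0 cells of a class leaves an interval that reaches 0.0716% on day 2 and 0.0349% on day 8.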

Other observations

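No test in this part was chosen after the result was seen, since it gives values and no explanation.

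Other lists fixed beforehand describe the time course further. Between days 2 and 16, gut and definitive endoderm genes were at least 2-fold higher in 5 of 6 measured members (median log2 ratio 3.52), with Foxa2, a pioneer factor of endoderm, from 1.18 to 19.8 CPM. Endothelium genes were higher in 7 of 10 and lower in none (median 2.27), with the receptor Kdr from 0.199 to 5.10 CPM and Ramp2 from 3.71 to 51.3 CPM. Cdh5 peaked on day 8 at 185 CPM. No cluster was named endothelium, and some of its genes were found in other classes on day 16. Cdh5 stood at 133 CPM in parietal endoderm, and Flt1 at 65.3 CPM in trophoblast and 83.4 CPM in visceral endoderm. TGF-beta and activin genes were higher in 8 of 13 and lower in none (median 1.67), with Inhba, an activin subunit, from 0.0362 to 32.3 CPM. Of BMP genes 3 of 13 were higher and 1 lower, with the antagonists Nog from 0.663 to 24.9 CPM and Grem1 from 0.241 to 9.32 CPM. FGF genes were higher in 4 of 12 and lower in none, with Fgf10 from 1.24 to 15.6 CPM, and WNT genes were higher in 6 of 14 and lower in 2, with Lef1 from 5.99 to 33.2 CPM. Formative epiblast genes were higher in 6 of 11 and lower in none (median 1.43), with Nodal from 3.87 to 12.3 CPM and Lefty1 from 29.0 to 216 CPM, and primitive streak genes were higher in 2 of 4.

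Neural plate border genes were higher in 5 of 13 and lower in 2 (median 0.87), with Zic1 from 0.284 to 8.99 CPM, and neural progenitor genes higher in 4 of 9 and lower in 2, with Six3, a forebrain factor, from 12.4 to 1.53 CPM. Of 5 glial genes 2 were higher and 1 lower. Cartilage genes were higher in 3 of 7 and lower in 1, with Col2a1, the main cartilage collagen, from 0.935 to 8.13 CPM, and the factor Sox6 from 103 to 24.7 CPM. Bone and tooth genes were higher in 2 of 5, with Runx2, the regulator of bone cells, from 1.67 to 7.21 CPM. Cardiomyocyte genes were higher in 4 of 8 and lower in 2, with Myl3 from 0.555 to 33.6 CPM and Tbx5 from 8.40 to 0.491 CPM. No cluster was named cardiomyocyte, and Myl3 was a leading gene of the parietal endoderm cluster, at 243 CPM there. Skeletal muscle genes were higher in 2 of 4 and lower in 1. Surface ectoderm genes were lower in 4 of 10 and higher in 2, erythroid genes higher in 2 of 3 and lower in 1, and of 2 measured myeloid genes 1 was higher. Germ cell genes were higher in 2 of 9 and lower in 1, with Stra8, a meiosis gene, from 6.20 to 38.1 CPM. Imprinted genes were higher in 5 of 17 and lower in 2, with Cdkn1c, an inhibitor of the cell cycle, from 15.8 CPM on day 2 to 251 on day 8 and 86.7 on day 16. Targets of p53 were higher in 3 of 14 and lower in none, with Gdf15, a stress cytokine, from 0.489 to 9.70 CPM. Of 20 S phase genes and 20 G2/M genes none passed 2-fold between days 2 and 16, and the G2/M median was −0.57 from day 2 to day 8 and 0.33 from day 8 to day 12.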
